A study of Homo sapiens with 4 samples.

How the data were processed

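Total RNA of 4 Jurkat lines was extracted with Trizol, biotin-labelled and hybridised to 1 Affymetrix human gene array each, per the labels' protocols. The lines carried an empty vector, Helios-1, Helios-d190-1186 or Helios-d326-1431, and each array was placed in its group by the transfection named in its label. The series matrix holds the values of all 4 arrays, and 0 of its columns were left unused. The deposited values are signal intensity on a linear scale, processed by the authors with MAS5 per the submitters' processing notes. MAS5 was designed for arrays with mismatch probes, which this type of array lacks, so how the values were summarised is uncertain. The version of MAS5, its scaling, its summary of probes into transcript clusters and the genome build are not given in the sources used here. The values include no detection calls, so signal cannot be told from background gene by gene.

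From there on, all steps were made on the deposited values without further scaling. Of 53617 transcript clusters, 16098 carried 1 gene symbol in the platform annotation used, 0 carried several and 37519 had no name there. All 16098 identifiers matched the RefSeq gene table of assembly GRCh38.p14, and 0 symbols needed an update. That table served only for names, gene type and gene span. It gives no transcript lengths, so span stands in for them. The 16098 clusters made 14884 genes, 779 of them with more than 1 cluster, and the cluster with the highest mean over the 4 arrays stood for its gene. Values identical to those of another cluster were found in 2128 clusters, 427 of them named, which points to shared probes.

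Intensities were compared as log2(intensity + 16), an offset that understates the changes of dim genes. A gene was kept when its highest array reached the median of all gene values, an intensity of 18.3, which left 7854 genes. A gene kept in this way can lie below the limit on the other arrays, where the size of its ratio is uncertain. With 1 array per line no test was run. A gene was counted as higher or lower when its log2 ratio reached 1 in size, and this rule of size describes the 4 arrays only. Against empty vector, the text names the 12 highest and 12 lowest genes that passed the filter, and in the other comparisons the 5 highest and 5 lowest. Symbols that begin or end like those of uncharacterised loci, microRNAs, small nucleolar, nuclear and other listed short RNAs or antisense RNAs were counted but not named by this rule; the SNAR genes, also small RNAs, lay outside that list of symbols and were named. Members of the gene lists at 2-fold, the extreme members of a described list and IKZF2 were also named. These rules, the 32 gene lists, the comparisons and the first set of alternatives were fixed before the data were examined. The lists cover T cell programmes, signalling, the cell cycle, stress, metabolism, chromatin partners, other cell types and housekeeping genes.

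For a list with at least 5 members past the filter, the median log2 ratio was set among 10000 random lists of the same size, matched on mean level in 10 bins, and called apart at or below percentile 2.5 or at or above 97.5. Correlations of ratios were taken across genes for the 3 ways of pairing 4 arrays that share none, and for ratios that share the empty vector array beside 100 simulations of unchanged lines. The steps were tested on simulated data with 7854 genes, with changes planted on a simulated Helios-1 array. The noise was sized from the middle spread of the Helios-d190-1186 ratios to empty vector, the quietest of these comparisons. Those ratios had an SD over genes of 0.165, against 0.186 for Helios-1 and 0.244 for Helios-d326-1431, so the recovery may be better than on the other arrays. The 2-fold rule recovered 20.9% of 67 genes planted at a log2 change of 1, 79.1% of 67 planted at 1.5 and 86.4% of 66 planted at 2, and counted 0 of 7654 unchanged genes. A planted list of 20 genes shifted by 0.3 came out at percentile 100, an unchanged list at 61.4, and 3 of 100 random lists were called apart. All these results hold for normal noise, which lacks the heavier tails of the real ratios. The 0 unchanged genes counted therefore says little about false counts on the real arrays.

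The alternatives were centring each array on its median, quantile normalization, no filter or one at the 75th percentile, the mean of a gene's clusters, all transcript clusters in place of genes, no offset or one of 50, and random lists matched in 20 bins or not at all. Chosen after the data were seen were random lists matched on level and gene span, a filter set without the Helios-d326-1431 array, and protein-coding genes of 10 kb or more only. For the match on span, the bins of level were fewer and those of span were broad. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.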

Results

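Gene expression was measured in Jurkat cells, an established human T lymphoblast leukaemia line, in 4 stable lines that carried an empty vector or 1 of 3 forms of Helios. Helios is the product of IKZF2 and a zinc-finger transcription factor of the Ikaros family, which acts in lymphocyte development. The forms were named Helios-1, Helios-d190-1186 and Helios-d326-1431, and the labels do not say what the numbers in the names of the last pair count. Each line was read on 1 array, so there were no replicates, no test between lines was possible and no p-value is given. Every difference below is therefore a difference between single arrays, and the number of arrays limits the precision of each value. The deposited values of the arrays were alike: the median intensity of the 53617 transcript clusters lay between 9.63 and 9.74, and the 75th percentile between 39.2 and 40.1. Processing before deposit may have made them so, and that median lies below the limit of 18.3 used for genes. Of 14884 genes, 7854 were bright enough on at least 1 array to be compared. Ratios are differences of log2(intensity + 16), and a gene was counted when its ratio reached 2-fold.

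IKZF2, the gene introduced, was not higher on any of the arrays labelled with a form of Helios. Its intensity was 358 on the array labelled empty vector, 294 on the array labelled Helios-1, 354 on the array labelled Helios-d190-1186 and 339 on the array labelled Helios-d326-1431. The log2 ratios of IKZF2 to empty vector were −0.27, −0.02 and −0.08 in that order. IKZF1, which encodes Ikaros, had intensities of 434, 476, 446 and 405 on the same arrays, and IKZF3 and IKZF4 stayed below the intensity limit of 18.3, at 5.60 to 8.03 and 7.37 to 8.20. Where the IKZF2 probes lie in the gene is not given in the sources used here, so a transgene lacking the probed parts would go unseen and the reading checks little. Below, the name of a line stands for the array so labelled, and each direction below rests on the labels alone.

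**Figure D1:**
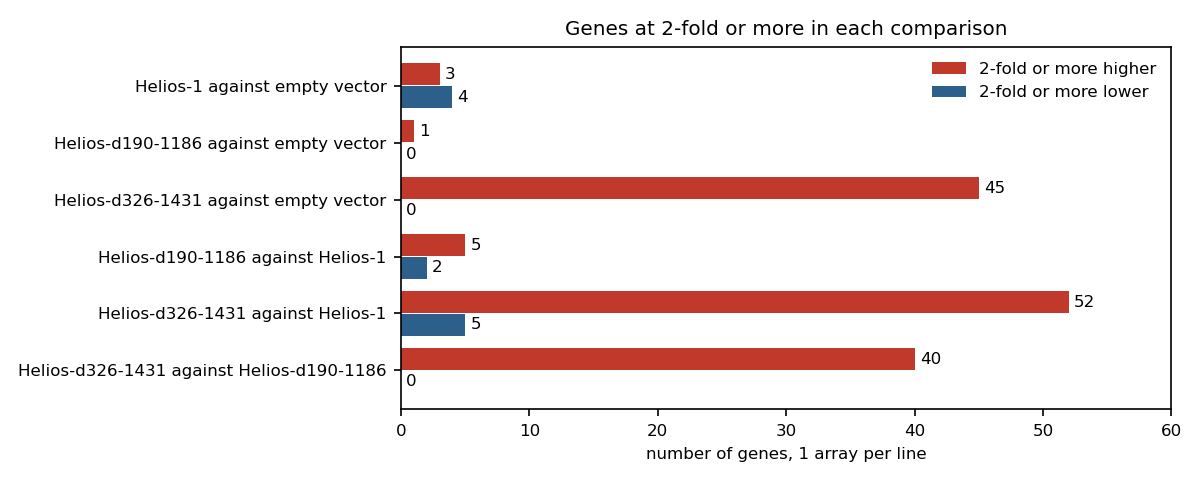
Number of genes (horizontal axis) at 2-fold or more higher (red) or lower (blue) in each of the 6 comparisons between single arrays, out of 7854 genes. The 3 comparisons that involve the array labelled Helios-d326-1431 hold 45, 52 and 40 higher genes, and the other 3 hold 3, 1 and 5.

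The first comparison set the array labelled Helios-1 against the array labelled empty vector, which asks how the cells with this form of Helios differed from cells without it. SACM1L, a phosphoinositide phosphatase of the endoplasmic reticulum and Golgi, was higher on the Helios-1 array (intensity 1279 against 623, log2 ratio 1.02). NETO1, a transmembrane auxiliary subunit of kainate receptors, and EPHA3, an ephrin receptor tyrosine kinase, were lower, at 58.8 against 169 (log2 ratio −1.30) and 56.6 against 152 (log2 ratio −1.21). In all, 3 of 7854 genes were higher and 4 lower at 2-fold. The other 4 fell outside the naming rule and were looked up after their values were seen: LOC100507412 (log2 ratio 1.27) and MIR4270 (1.13) were higher, and MIR1299 (−1.23) and MIR328 (−1.11) lower. With an offset of 50 in place of 16, SACM1L (0.98) and EPHA3 (−0.93) were short of 2-fold. MIR4270 read 16.1 on the empty vector array and MIR328 8.14 on the Helios-1 array, below the limit of 18.3, so the size of their ratios is uncertain.

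Below 2-fold, the highest ratios of the naming rule on the Helios-1 array belonged to the RING-finger gene RNF150 (0.95), the calpain-like gene CAPN6 (0.89), the chemokine receptor CXCR3 (0.81), the chaperone HSPA4L (0.80) and KCTD12 (0.80). CXCR3 read 71.9 against 34.2 and HSPA4L 504 against 282. They were followed by the tetherin gene BST2 (0.75), the kinase MAST3 (0.74), TMC7 (0.72), the T cell surface gene CD7 (0.71, 831 against 501), GPR157 (0.71) and the transcription factor ATF5 (0.70). Among the lowest were the adhesion gene NECTIN3 (−0.998, just short of 2-fold), the zinc-finger genes ZNF85 (−0.86) and ZNF680 (−0.72), ZBTB16 (−0.72), which encodes the transcription factor PLZF, and TMEM89 (−0.73). FAM86B2-DT (−0.95), SEPTIN7P14 (−0.93), RPL23AP32 (−0.86), DSTNP2 (−0.74) and WASH3P (−0.71) belonged to a divergent transcript and pseudogenes, which share sequence with other genes and are uncertain. Below the limit of 18.3 lay CAPN6 (8.58) and TMC7 (15.1) on the empty vector array and NECTIN3 (15.8) and RPL23AP32 (14.3) on the Helios-1 array, so the size of their ratios is uncertain too.

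Of the gene lists, cholesterol biosynthesis stood farthest from its random lists on the Helios-1 array. The median log2 ratio of its 16 measured members was −0.26, lower than all 10000 random lists of like level (percentile 0), and 14 of the 16 were below 0 with none at 2-fold. HMGCS1, which makes the precursor of mevalonate, read 354 against 505 (−0.49), MVK −0.38 and the cholesterol carrier STARD4 −0.37. PMVK, also an enzyme of the mevalonate pathway, went the other way (0.45). Heat shock genes had a median of 0.17 (percentile 98.8), with 8 of 8 members above 0. HSPA1A and HSPA1B led it at 0.46 each, and these near-identical genes cannot be separated with certainty by their probes. Genes of the T cell receptor complex and coreceptors had a median of 0.14 (percentile 99.3, 10 of 14 above 0), from CD7 (0.71), CD2 (0.40) and CD5 (0.39) to the adaptor TRAT1 (−0.36). Notch pathway targets had a median of 0.15 (percentile 99), with PTCRA, the pre-T-cell receptor alpha chain, at 0.36, NOTCH3 at 0.25 and TRIB2 at −0.39. The T cell receptor and Notch lists were also above 0 on the Helios-d190-1186 array, at 0.09 (percentile 94.2) and 0.13 (percentile 96.96). On the Helios-d326-1431 array they read −0.01 and −0.11. Neither list stood apart between Helios-d190-1186 and Helios-1 (percentiles 23.7 and 4.53). The ratios of both arrays to empty vector share the empty vector array. These values therefore cannot tell whether the shifts are particular to the Helios-1 array. Interferon response genes had a median of 0.12 (percentile 97.7), with BST2 at 0.75, SAMD9L at 0.42 and RSAD2 at −0.31. Ribosomal protein genes had a median of −0.07 (percentile 0.515), with RPL27 at −0.50, RPS9 at −0.27 and RPL19 at 0.12. No member of these lists reached 2-fold. Without the filter on dim genes the percentiles of the T cell receptor, Notch and interferon lists were 95.05, 68.4 and 94.0, inside the range of random lists, and the interferon list also lay inside it after quantile normalization (96.7) and with 20 level bins (96.8). With random lists matched on span, chosen after the data were seen, the interferon list lay at percentile 96.5, and under a stricter filter the Notch list lay at 76.7. The random lists describe these arrays only and stand in for no replicate.

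**Figure D2:**
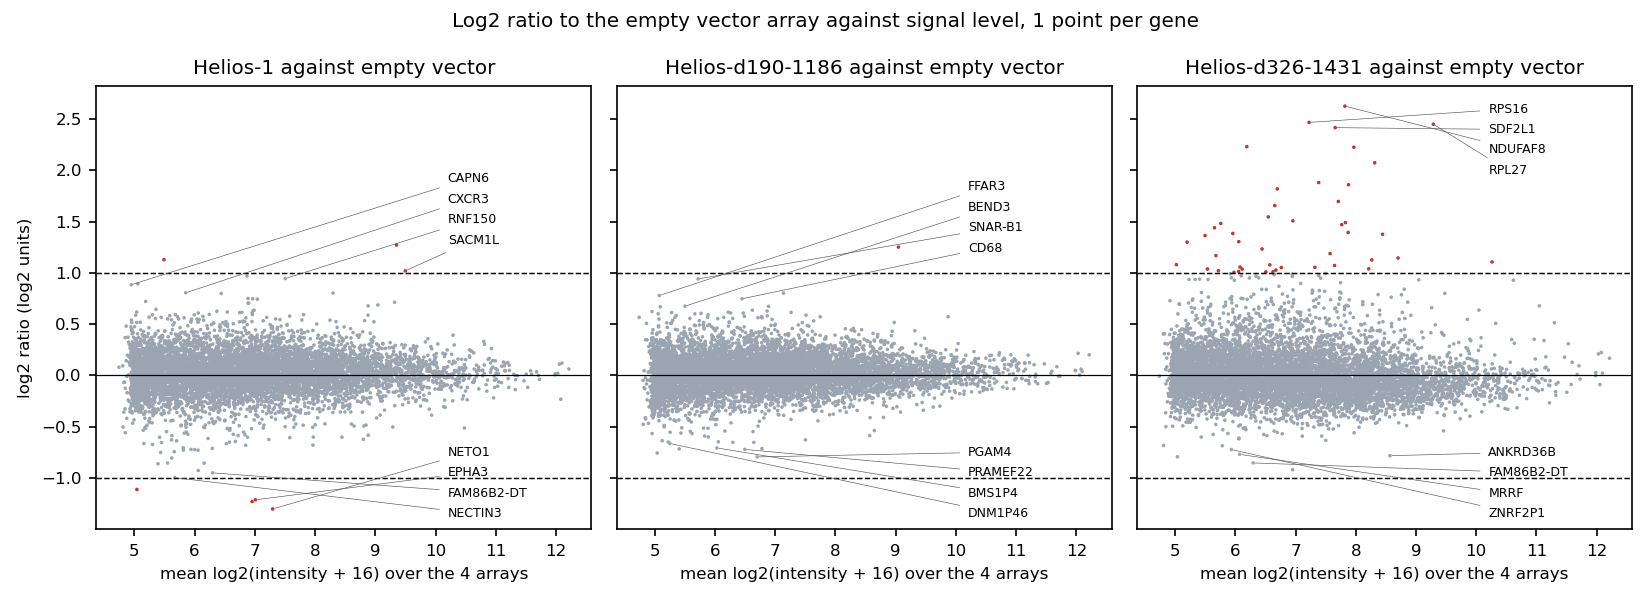
Log2 ratio to the empty vector array (vertical axis, log2 units) against mean log2(intensity + 16) over the 4 arrays (horizontal axis, log2 units), 1 point per gene for 7854 genes, with red points at 2-fold or more and dashed lines at 2-fold. The highest and lowest genes of the naming rule are marked, and the spread of the ratios over genes (SD) is 0.19, 0.16 and 0.24 from left to right.

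The array labelled Helios-d190-1186 differed least from the array labelled empty vector. Only 1 of 7854 genes passed 2-fold, the microRNA locus MIR3143 (803 against 328, log2 ratio 1.25), which lay outside the naming rule and was looked up after its value was seen. Among the genes of the rule none reached 2-fold. The highest were SNAR-B1, a small noncoding RNA (0.94), the short-chain fatty acid receptor FFAR3 (0.78) and the lysosomal macrophage marker CD68 (0.75, 98.8 against 52.3). BEND3 (0.68), BARHL2 (0.67), NAGPA (0.64), GAS7 (0.63), TMEM14B (0.62), the RNA-binding gene RBM38 (0.62), FCGBP (0.61), ZC3H10 (0.61) and ZNF417 (0.61) came next. The lowest were PGAM4 (−0.80, 51.9 against 102), PRAMEF22 (−0.72), BMS1P4 (−0.71), DNM1P46 (−0.66), ZNF805 (−0.65), FAM86B2-DT (−0.65), ZFP1 (−0.63) and the Notch target HES4 (−0.60, 29.0 against 52.3). ANKRD36B (−0.59), WDR5CP (−0.55), LCE3B (−0.54) and WASH3P (−0.51) completed the set. PGAM4, PRAMEF22 and the SNAR genes have near-identical relatives, so their values are uncertain, as are the ratios of genes below 18.3 on 1 of these arrays: FFAR3 (10.4) and FCGBP (17.4) on the empty vector array, DNM1P46 (15.6) and WDR5CP (13.6) on the Helios-d190-1186 array.

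T cell activation genes had the most distant list on the Helios-d190-1186 array, with a median of 0.21 over 8 members (percentile 99.7, 6 of 8 above 0). CD5 read 0.38, DUSP2 0.26 and MYC 0.26, while EGR1 read −0.36 and CD69 −0.34. NK and cytotoxic markers had a median of 0.19 over 7 members (percentile 98.9), with TBX21 at 0.33, NKG7 at 0.22 and CST7 at 0.20, and CCL5 at −0.26. TBX21 read 22.1 against 14.3, NKG7 90.6 against 75.7 and CST7 240 against 207, and T cells also express several of these genes. Cholesterol biosynthesis genes had a median of −0.06 (percentile 1.37), with HMGCS1 at −0.26, STARD4 at −0.22 and HSD17B7 at 0.46. Oncogenes and tumour suppressors of T-cell acute lymphoblastic leukaemia had a median of −0.06 (percentile 2.09), between WT1 at −0.21 and GATA3 at 0.28. No member of these lists reached 2-fold. Without the filter on dim genes the NK and cytotoxic markers lay at percentile 79.2, and under a stricter filter the median of the leukaemia genes was above 0, at 0.0036, while without matching on level their percentile was 2.72. Directions again rest on the labels.

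The array labelled Helios-d326-1431 stood apart from the array labelled empty vector, with 45 of 7854 genes higher at 2-fold and 0 lower. NDUFAF8, an assembly factor of respiratory complex I, had the highest ratio (intensity 785 against 114, log2 ratio 2.63). The ribosomal protein genes RPS16 (508 against 78.6, log2 ratio 2.47), RPL27 (2355 against 417, log2 ratio 2.45) and RPS21 (446 against 109, log2 ratio 1.88) were also higher. So were SDF2L1, a chaperone component of the endoplasmic reticulum (658 against 110, 2.42), and the ubiquitin-like genes ISG15 (206 against 31.2, 2.23) and SUMO2 (808 against 160, 2.23). The naming rule also gave UQCRHL, a copy of the complex III hinge gene UQCRH (2.08), the selenoprotein SELENOH (1.86), NUDT1, which clears oxidised nucleotides (1.82), the mitochondrial import gene TIMM13 (1.70) and the centromere gene CENPW (1.66). UQCRHL and the ribosomal protein genes share sequence with close copies and are uncertain. The lowest genes of the rule, none at 2-fold, were FAM86B2-DT (−0.85), ANKRD36B (−0.78), the mitochondrial ribosome recycling factor MRRF (−0.77), ZNRF2P1 (−0.72), SNAR-D (−0.68), ZFP1 (−0.63), the ubiquitin ligase scaffold CUL4B (−0.59), ANKRD12 (−0.59), PEX5L (−0.59), RPL32 (−0.58), ZKSCAN4 (−0.57) and ZC3H13 (−0.56), a component of the RNA m6A methylation machinery. SNAR-D read 7.31 on the Helios-d326-1431 array, below the limit, so its ratio is uncertain.

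Ribosomal protein genes had a median log2 ratio of 0.29 on the Helios-d326-1431 array, above all 10000 random lists (percentile 100). Of 23 members past the filter 21 were above 0 and 2 were at 2-fold, RPS16 and RPL27; RPS21 is not in the list. Other members were RPL11 at 0.95, RPS19 at 0.93 (2526 against 1319) and RPL32 at −0.58. Genes of oxidative phosphorylation had a median of 0.19 (percentile 99.9), with 10 of 11 members above 0 and none of these at 2-fold, and ranged from UQCRH (0.75) and COX7A2 (0.62) to UQCRC2 (−0.06). UQCRHL and COX7B, a subunit of complex IV looked up after its value was seen (1.02, 96.0 against 39.4), were at 2-fold but are not in the list. The other list members at 2-fold were ISG15, SDF2L1 and PMVK (1.39, 94.7 against 26.4), each in a list that did not stand apart. The interferon list had a median of −0.04 and a mean of 0.17 (percentile 21.0), the endoplasmic reticulum stress list −0.06 and 0.29 (percentile 42.5), so median and mean differed in sign in both, and the cholesterol list had a median of 0.02 (percentile 84.4).

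Ratios on the Helios-d326-1431 array ran with the genomic span of the gene. Protein-coding genes that span under 2 kb had a median log2 ratio of 0.15 (157 genes), those of 2 to 5 kb 0.09 (546 genes), those of 30 to 100 kb −0.06 (2319 genes) and those of 100 kb or more −0.09 (1164 genes). Across the 7102 protein-coding genes, which are not independent replicates, Spearman's rho of span and ratio was −0.37, against −0.05 on the Helios-1 array and −0.10 on the Helios-d190-1186 array. The 38 protein-coding genes higher at 2-fold had a median span of 5.02 kb, against 29.2 kb over all, and 19 of the 38 spanned less than 5 kb, among them RPS16 (2.81 kb), SDF2L1 (1.998 kb) and ISG15 (1.04 kb). With protein-coding genes of 10 kb or more only, a restriction chosen after the trend was seen, 12 genes were higher. With random lists matched on span as well, also chosen afterwards, the oxidative phosphorylation list fell inside the random range, at percentile 97.1.

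**Figure D3:**
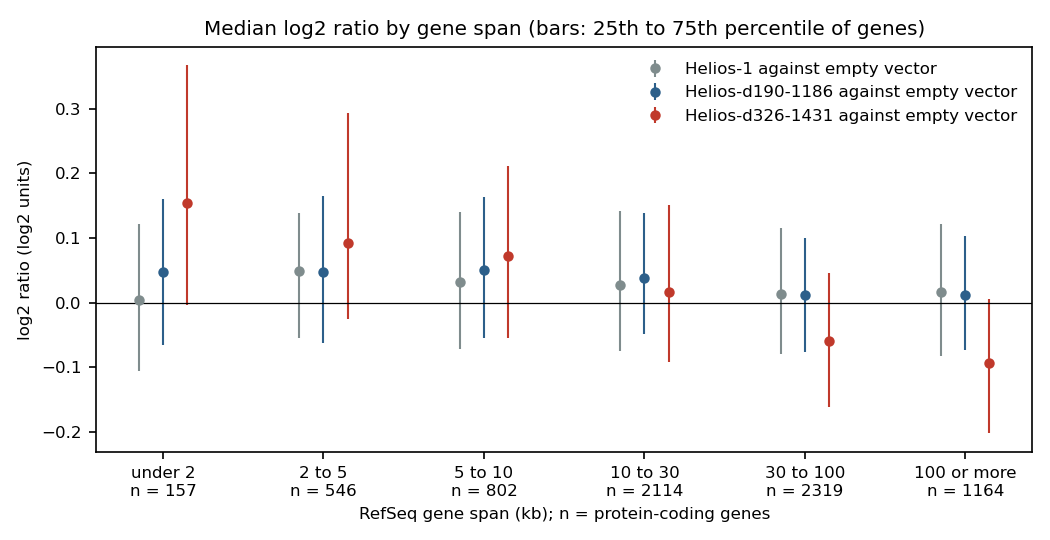
Median log2 ratio to the empty vector array (vertical axis, log2 units) of protein-coding genes grouped by RefSeq gene span (horizontal axis, kb, with the number of genes), in grey for Helios-1, blue for Helios-d190-1186 and red for Helios-d326-1431, with bars from the 25th to the 75th percentile of genes. On the Helios-d326-1431 array the medians run from 0.15 under 2 kb to −0.09 at 100 kb or more.

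The arrays of the d-named forms were then set against the array labelled Helios-1, which asks how these forms differ from it. On the Helios-d190-1186 array 5 genes were higher and 2 lower at 2-fold. NETO1 (1.51), EPHA3 (1.27), SNAR-B1 (1.12) and ZBTB16 (1.04) were higher, with ZNF429 at 0.98, and SACM1L was lower (−1.11), with RNF150 at −0.997, PRAMEF22 at −0.91, HSPA4L at −0.87 and HSPA1B at −0.75. MIR1299 (1.05) and LOC100507412 (−1.27), outside the naming rule and looked up afterwards, made up the rest. With an offset of 50, EPHA3 (0.97), SNAR-B1 (0.67) and ZBTB16 (0.66) were short of 2-fold, as was SNAR-B1 (0.93) with the mean of its clusters. SNAR-B1 read 18.1 on the Helios-1 array, below the limit. Heat shock genes had a median of −0.20 (percentile 0.060, 0 of 8 above 0) and cholesterol biosynthesis genes one of 0.19 (percentile 100), with MVK at 0.58, SREBF2, the regulator of the pathway, at 0.37 and PMVK at −0.07. Ribosomal protein genes had a median of 0.11 (percentile 99.8), with RPL27 at 0.67, RPS16 at 0.63 and RPL19 at −0.06. NF-kappaB targets had a median of 0.20 (percentile 99.2), with CD83 at 0.34, IER3 at 0.29 and CCL5 at −0.37, and early thymocyte genes one of 0.12 (percentile 98.6), with CD38 at 0.51, CD34 at 0.48, CD1B at 0.45 and CD1D at −0.32. Without the filter on dim genes the NF-kappaB median was −0.01, and with random lists matched on span, chosen after the data were seen, the thymocyte genes lay at percentile 97.3.

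Against the array labelled Helios-1, the Helios-d326-1431 array had 52 genes higher and 5 lower at 2-fold. RPL27 (2.95), RPS16 (2.70), UQCRHL (2.40), SUMO2 (2.39) and ISG15 (2.27) had the highest ratios, and SACM1L (−1.24), HSPA4L (−1.23) and RNF150 (−1.07) were lower, with CXCR3 and SNX29 at −0.92 each. LOC100507412 (−1.33) and MIR637 (−1.23), outside the naming rule and looked up afterwards, were the other lower genes. With an offset of 50, RNF150 (−0.92) was short of 2-fold. Cholesterol biosynthesis genes had a median of 0.27 (percentile 100, 15 of 16 above 0), with PMVK at 0.94, ACAT2 at 0.65, FDPS at 0.62 and HSD17B7 at −0.07. Heat shock genes had a median of −0.31 (percentile 0.090, 0 of 8 above 0), led by HSPA1A (−0.72) and HSPA1B (−0.63). Ribosomal protein genes had a median of 0.27 (percentile 100), with its members RPL27, RPS16 and RPL11 (1.18) at 2-fold. RPS21 (2.12) and RPS15A (1.21), also at 2-fold, are not in the list, and RPS15A was looked up afterwards. Oxidative phosphorylation genes had a median of 0.23 (percentile 99.9), from UQCRH (0.76) to COX6C (0.02). Cytokine receptor and JAK-STAT genes had a median of −0.15 (percentile 1.70), from IL9R (−0.63) to TYK2 (0.29), but lay at percentiles 15.9 without the filter on dim genes, 69.5 under a stricter one and 3.18 without matching on level. With protein-coding genes of 10 kb or more only, a limit chosen after the data were seen, 16 genes differed at 2-fold.

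Between the arrays labelled Helios-d326-1431 and Helios-d190-1186, 40 genes were higher on the first and 0 lower. NDUFAF8 (2.41), SDF2L1 (2.32), RPL27 (2.29), SUMO2 (2.26) and RPS16 (2.06) had the highest ratios. SNX29 (−0.70), BARHL2 (−0.64), ANTXR1 (−0.62), the progenitor marker CD34 (−0.61) and TPTEP2 (−0.61) had the lowest among genes of the rule, with CD34 below the limit on the first array, at 10.8. With protein-coding genes of 10 kb or more only, 9 genes were higher.

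Set against each of the other arrays at once, 28 genes were 2-fold higher on the Helios-d326-1431 array alone and 0 were lower. On the Helios-1 array SACM1L and LOC100507412 were higher than on each other array and NETO1 was lower, and the arrays labelled empty vector and Helios-d190-1186 had no such gene. Ratios that share no array correlated weakly across the 7854 genes, which are not independent replicates. Pearson's r was −0.08 (Spearman's rho −0.09) for Helios-1 over empty vector with Helios-d326-1431 over Helios-d190-1186, 0.05 (0.06) for Helios-d190-1186 over empty vector with Helios-d326-1431 over Helios-1, and 0.13 (0.14) for Helios-d326-1431 over empty vector with Helios-d190-1186 over Helios-1. Ratios that share the empty vector array correlated at 0.45 between Helios-1 and Helios-d190-1186, 0.23 between Helios-1 and Helios-d326-1431 and 0.40 between Helios-d190-1186 and Helios-d326-1431, while simulated unchanged lines gave 0.50. Their covariances were 0.0138, 0.0102 and 0.0161, against 0.0111 in the simulation, differences of 0.0027, −0.00083 and 0.0050. The simulated noise was sized from the middle spread of the Helios-d190-1186 ratios and lacks their tails, which the measured covariances include. The differences therefore cannot be read as shared changes. The single empty vector array cannot be split, so part of any excess may come from it.

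**Figure D4:**
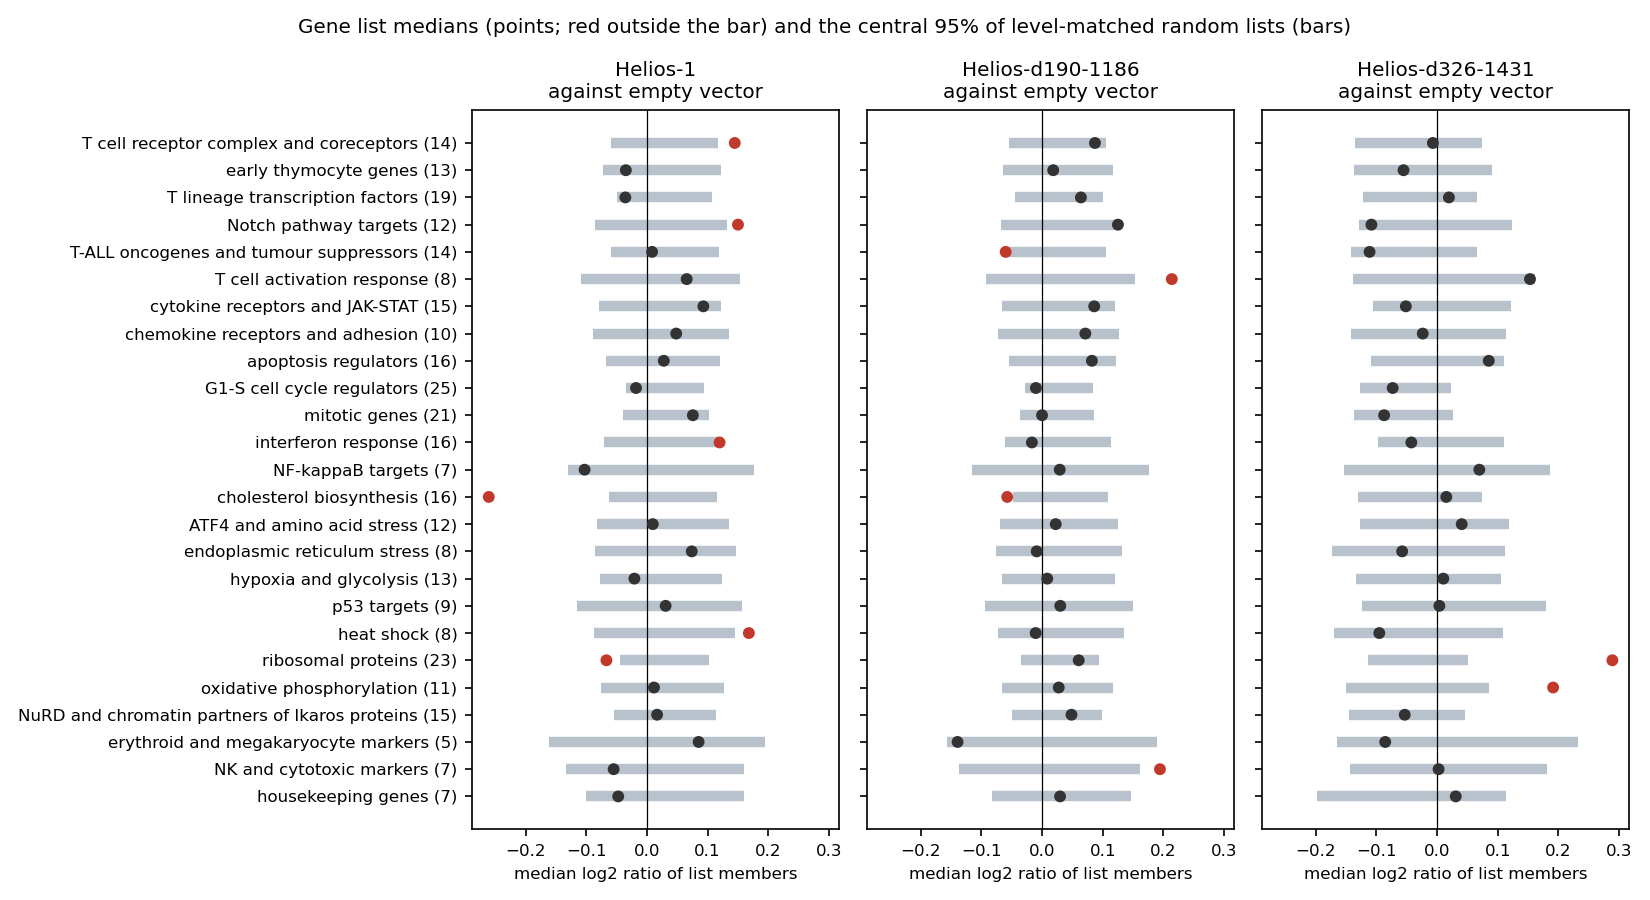
Median log2 ratio to the empty vector array (horizontal axis, log2 units) of each gene list (number of members past the filter in brackets), with grey bars for the central 95% of 10000 level-matched random lists and red points outside them. Cholesterol biosynthesis lies at −0.26 on the Helios-1 array and ribosomal proteins at 0.29 on the Helios-d326-1431 array.

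Over 25 lists and 5 comparisons, 22 of 125 list medians lay outside the central 95% of random lists. Chance gives about 6.25 only if the members of a list vary as independently as the unrelated genes of a random list. Members of a list can vary together, so more medians may fall outside without any effect of a line. The comparisons also share the empty vector and Helios-1 arrays, so a departure of 1 array can count in several. The 22 therefore cannot be read as an excess over chance. Against empty vector the remaining lists stayed inside the central 95%. On the arrays labelled Helios-1, Helios-d190-1186 and Helios-d326-1431 the medians were −0.04, 0.06 and 0.02 for T lineage transcription factors, 0.05, 0.07 and −0.02 for chemokine receptors and adhesion, and 0.03, 0.08 and 0.09 for apoptosis regulators. Early thymocyte genes had medians of −0.03, 0.02 and −0.06, NF-kappaB targets −0.10, 0.03 and 0.07, and cytokine receptors and JAK-STAT genes 0.09, 0.09 and −0.05. T cell activation genes had medians of 0.07 on the Helios-1 array (percentile 75.3) and 0.15 on the Helios-d326-1431 array (percentile 97.03). Regulators of G1 and S phase had medians of −0.02, −0.01 and −0.07, with PCNA at 0.66 on the Helios-d326-1431 array, and mitotic genes 0.08, 0.00 and −0.09. The medians were 0.01, 0.02 and 0.04 for ATF4 and amino acid stress, −0.02, 0.01 and 0.01 for hypoxia and glycolysis, and 0.03, 0.03 and 0.00 for p53 targets, with BAX at 0.53 on the Helios-d326-1431 array. NuRD and other chromatin partners of Ikaros proteins had medians of 0.02, 0.05 and −0.05, with HDAC1 at −0.33 on the Helios-1 array. Housekeeping genes had medians of −0.05, 0.03 and 0.03. Erythroid and megakaryocyte markers had medians of 0.09, −0.14 and −0.09. Too few members passed the filter in 7 lists, so only values are given for them. FOXP3 of the regulatory T cell genes read 0.11, −0.02 and 0.07 on the Helios-1, Helios-d190-1186 and Helios-d326-1431 arrays and CCR8 0.30, −0.11 and −0.09, and of the antigen presentation genes B2M read −0.26, 0.07 and 0.72 and TAPBP 0.54, 0.12 and 0.07. Markers of other cells showed no member at 2-fold: of the B cell markers IGLL1 read 0.53, 0.48 and 0.77 on the 3 Helios-labelled arrays, BLK 0.01, −0.21 and −0.07 and CR2 −0.15, −0.02 and 0.11. Of the myeloid markers CD68 read 0.23, 0.75 and 0.44 and SPI1 −0.08 on each, and of the adherent and epithelial markers VIM read −0.11, 0.14 and 0.14, KRT18 0.10, −0.08 and 0.06 and THY1 0.00, −0.08 and −0.22. No replication-dependent histone gene was measured under a name, and IKZF1 and IKZF2 of the Ikaros family are given above.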

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

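No test was run on the values in this part, and the 4 clusters named by number were picked after their values were seen. The comparisons of genes leave out the 37519 transcript clusters without a name in the annotation used, and some of these carried signal above the empty vector array. Of the 11452 that passed the same intensity limit, 54 were higher at 2-fold and 116 lower on the array labelled Helios-1, 71 higher and 88 lower on the array labelled Helios-d190-1186, and 229 higher and 95 lower on the array labelled Helios-d326-1431. On the Helios-d326-1431 array cluster 16736212 read 1713, against 28.5 on the empty vector array, 12.1 on the Helios-1 array and 8.50 on the Helios-d190-1186 array, and cluster 16839474 read 2767, against 97.2, 89.4 and 148. Cluster 16735827 read 15.1 on the Helios-1 array and 1619, 996 and 1048 on the empty vector, Helios-d190-1186 and Helios-d326-1431 arrays. Cluster 16900524 read 21.5 on the Helios-d190-1186 array and 1401, 1188 and 1107 on the empty vector, Helios-1 and Helios-d326-1431 arrays.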

How the results depend on the processing

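The limits to genes of 10 kb or more, the filter set without the Helios-d326-1431 array and the random lists matched on gene span were chosen after the data were seen. In the order Helios-1, Helios-d190-1186 and Helios-d326-1431 against empty vector, Helios-d190-1186 and Helios-d326-1431 against Helios-1, and Helios-d326-1431 against Helios-d190-1186, 7, 1, 45, 7, 57 and 40 genes stood at 2-fold. With no offset there were 39, 20, 90, 40, 134 and 79, since dim genes then weigh fully, and without detection calls their signal cannot be told from background. An offset of 50 gave 2, 1, 22, 3, 31 and 22. Transcript clusters in place of genes gave 178, 160, 369, 173, 387 and 339, out of 30887 that passed the median of all cluster values, an intensity of 9.68. Of these, 170, 159, 324, 166, 329 and 299 had no name and 8, 1, 45, 7, 58 and 40 had one. Clusters without names therefore made up nearly all of the rise. The count below the limit of 18.3 used for genes was 0, which tests nothing. With the offset of 16, no cluster wholly below that limit can reach 2-fold. Genes of 10 kb or more gave 12, 16 and 9 in the comparisons of the Helios-d326-1431 array with empty vector, Helios-1 and Helios-d190-1186, out of 5597 genes. Centring, quantile normalization, both other filters, the mean of clusters and, for the 3 comparisons without the Helios-d326-1431 array, the filter set without it kept each count within 1.5 times. Leaving out the filter could not change a count, since no gene wholly below 18.3 can reach 2-fold with the offset of 16. Centring and quantile normalization could change little, as the arrays already had like medians and quartiles.

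Of 102 named ratios, 33 stood at 2-fold, and 0 of 510 values under 5 alternatives changed sign. That 0 says little, since a change of offset cannot reverse a cluster's ratio and the genes were picked for the size of their ratios. With no offset, 29 of the other ratios reached 2-fold, and with an offset of 50, 6 of the 33 fell short. After centring 1 ratio and after quantile normalization 2 more reached it, and with the mean of clusters 1 fell short. Over 7 alternatives the correlations without a shared array, in the order of the report, ran from −0.105 to −0.0708, from 0.0393 to 0.0822 and from 0.112 to 0.181, each farthest from 0 under the filter at the 75th percentile. Of the 22 list medians called apart, between 16 and 22 stayed so under the 7 alternatives tried on them. The leukaemia genes on the Helios-d190-1186 array against empty vector changed sign under the filter at the 75th percentile (0.00362), and the NF-kappaB targets on the Helios-d190-1186 array against Helios-1 without a filter (−0.0106); the cause was not tested. Under the filter at the 75th percentile some of these lists had fewer than 5 members and gave no value.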

Other observations

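The tests of array scaling and of the ribosomal protein genes as a class, and the test of exchanged labels, were chosen after the results they concern were seen, and those matched on gene span or run without the ribosomal protein and oxidative phosphorylation genes were added once the trend with span was known.

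The first pattern weighed is the set of short genes higher on the array labelled Helios-d326-1431. Scaling between arrays is argued against, since it would move genes of like level together: the 45 genes higher had a median log2 ratio of 1.31, and the 200 genes nearest in level to each had one of −0.0037. With only 45 of 7854 genes at 2-fold, that second median had little room to move, so the test adds little to the count itself. A hypothesis of size-dependent recovery of short RNAs, for instance from a difference in RNA quality or handling, stays open: genes with a span under 2 kb lay at percentile 100 of level-matched random lists, still at percentile 100 without ribosomal protein and oxidative phosphorylation genes, and the histone genes meant as a further test had 0 members measured. A movement of the ribosomal protein genes as a class also stays open, since they lay at percentile 100, and at percentile 99.98 among random lists matched on level and span. That matching used broad bins of span, so part of the trend with span may remain within a bin. The percentile therefore cannot separate a movement of the class from that trend. Span is not transcript length, and an effect of the Helios-d326-1431 form was not tested, since only 1 array carried it.

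The second pattern weighed is that IKZF2 was not higher on the arrays labelled with Helios. An exchange of labels among the 4 arrays is argued against as the cause, since IKZF2 ranged over 0.27 log2 units and no assignment of the labels would put a Helios line well above empty vector. Probes outside the introduced sequence and weak expression of the transgene stay open and were not tested. IKZF2 therefore cannot check the labels either, and the directions in the report still rest on them. No other gene in the data is known from the labels to mark a line, and no biological explanation was tested.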
